A study of Mus musculus with 8 samples.

How the data were processed

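Total RNA was extracted from FACS-sorted mammary basal cells of 10-week-old female mice and sequenced single-end on an Illumina instrument, per the labels' protocols. The 8 libraries fall into 4 populations by title, with 2 libraries each. The labels record a batch of 1 or 2 for each library, equal to the replicate number and balanced over the populations. The deposited tables hold the authors' raw counts of reads per gene for 27164 Entrez genes, with gene lengths, and these counts had not been normalized. The submitters' processing notes name CASAVA 1.8.2, featureCounts, edgeR 3.10.2, limma 3.24.14 and the mouse genome mm10 (GRCm38), with no roles or order. The aligner is not given in the sources used here, nor is whether counting used the strand, so genes that overlap or have near-identical copies are uncertain. Symbols and coordinates came from RefSeq for GRCm38.p6, matched by Entrez identifier for 25260 genes. Identifiers without a match held 2.56 to 2.86% of the counts of a library.

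Total counts ran from 24571300 to 38384875 per library, and the 10 most abundant genes took 4.21 to 5.05% of them. A floor of 3 counts corresponds to 0.0782 CPM in the largest and 0.122 CPM in the smallest library. Replicates were tested for being 1 library deposited again, and the chi-square statistic per degree of freedom was 36.0 to 57.3 within populations, far above sampling noise. Libraries with the same number deviated together from their population means, with r across genes of 0.415 to 0.55 over 6 pairs of populations, so the batch stated in the labels pairs the libraries. Normalization factors were 0.935 to 0.959 in batch 1 and 1.02 to 1.07 in batch 2. The common biological coefficient of variation was 0.0928 with batch in the model and 0.192 without it.

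The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3, robust) on the raw counts of all 8 libraries, with TMM normalization, filterByExpr with a minimum count of 10 and a model of population plus batch, which left 3 residual degrees of freedom. Of the genes in the tables, 16526 were tested and 10638 were left out by the filter. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, with a threshold of 0.05, and tests were two-sided. The comparisons were the Tspan8 effect, the Lgr5 effect, their interaction, the 4 simple effects of 1 marker at a level of the other, Lgr5+T8hi against Lgr5-T8-, and Lgr5+T8hi against the mean of the other 3. CPM values used the TMM-adjusted library sizes.

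Gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. Lgr5 and Tspan8 were always named. For the Tspan8 effect, the Lgr5 effect and Lgr5+T8hi against the other 3, the 10 highest and 10 lowest log2 fold changes were taken among genes past the threshold, with a mean of at least 5 CPM and the same sign in both batches. For the interaction and simple effects 3 per direction were taken. From each list, examples were drawn from the 4 members with the smallest adjusted p. Predicted and unnamed genes were skipped in the top genes. Of 35 lists, 33 were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The 2 sort genes were not tested as a list. The list of mitochondrially encoded genes had 0 members in the tables. The lists held basal, contractile, luminal, stem cell, matrix and signalling genes and markers of other cell types.

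The test was checked on simulated counts drawn from the real means, library sizes and spread, with 200 genes of at least 5 mean CPM changed. A simulated list of 20 members shifted 1.5-fold had a camera adjusted p of 8.71e-118 with the preset and 0.00277 with an estimated correlation, and 0 of 20 unshifted lists were called by either. For the Tspan8 effect, 16347 and 16321 genes passed the filter in the 2 simulations, and 93.5% of the genes changed 1.5-fold and 99.0% of those changed 2-fold were recovered. For the Lgr5 effect these were 16328 and 16349 genes, 93.5% and 100.0%. For Lgr5+T8hi against the other 3 they were 16336 and 16339 genes, 87.5% and 98.5%. For the interaction these were 16336 and 16325 genes, 22.0% and 84.5%. Recovery below 5 CPM was not simulated (immune list median 1.88). Among unchanged genes 4.60 to 5.40% had a p under 0.05, but false calls made up 7.89 to 14.9% of all calls at a nominal rate of 5%, and 8.33 to 13.9% with limma-voom. Alternatives were a fit without the batch block, RLE normalization, no count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, an estimated correlation for the lists, and leaving out each library in turn. After the data had been seen, 1 alternative was added, limma-voom without the block, because edgeR without the block called 0 genes in 1 comparison. Leaving out a library left a population with 1 library, which was then assumed to vary like the others.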

Results

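Gene expression was measured by single-end RNA sequencing in basal cells of the mammary gland, the outer, contractile layer of the milk ducts, sorted from 10-week-old female C57BL/6 mice that carry the Lgr5-GFP-IRES-CreERT2 allele. In these mice green fluorescent protein is made from the locus of Lgr5, a receptor for R-spondins that marks stem cells in several epithelia. The second sort marker was Tspan8 (T8), a tetraspanin, which is a membrane protein with 4 transmembrane helices. The 4 populations were Lgr5+T8hi, Lgr5-T8hi, Lgr5+T8- and Lgr5-T8-, each with 2 libraries, 1 from each of 2 batches. The total gene counts in batch 1 were 36175181 for Lgr5+T8hi, 38384875 for Lgr5-T8hi, 33976135 for Lgr5+T8- and 34490324 for Lgr5-T8-. In batch 2 they were 24662492, 35121694, 24571300 and 25904146 in the same order. Between 18637 and 19771 genes had at least 1 count in a library. A count of 0 allowed a level of up to 0.122 CPM (counts per 1000000 counts) in the smallest library, which covers counting error only. The labels do not say whether the 2 libraries of a population came from separate mice, so p-values measure the spread between these samples, which may be technical. Levels are CPM with the SD over 2 libraries (n = 2), and changes are log2 fold changes ± standard error over all 8 libraries.

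The 2 sort markers were examined first, because they check the labels. Tspan8 (Entrez 216350, chromosome 10, 115816817 to 115849893, GRCm38.p6) stood at 275 ± 19.5 CPM in Lgr5+T8hi, 159 ± 11.7 in Lgr5-T8hi, 8.70 ± 2.66 in Lgr5+T8- and 3.76 ± 0.851 in Lgr5-T8- cells. Its log2 difference between the T8hi and the T8- populations was 5.20 ± 0.10 (edgeR adjusted p = 3.74e-11). Lgr5 (Entrez 14160, chromosome 10, 115450314 to 115587780) stood at 184 ± 13.5, 124 ± 6.62, 199 ± 19.4 and 54.4 ± 5.55 CPM in the same order, and its difference between Lgr5+ and Lgr5- populations was 1.21 ± 0.08 (edgeR adjusted p = 3.69e-06). Lgr5-T8hi cells thus held Lgr5 transcripts at a level 1.18 ± 0.11 log2 units above Lgr5-T8- cells (edgeR adjusted p = 5.68e-05), while Lgr5+T8hi and Lgr5+T8- cells differed by -0.11 ± 0.11 (edgeR adjusted p = 0.615). The difference between these 2 effects was -1.30 ± 0.15 (edgeR adjusted p = 0.00164). Tspan8 was also higher in Lgr5+ than in Lgr5- populations, by 1.00 ± 0.10 (edgeR adjusted p = 5.16e-05). Because cells were gated on both markers, their differences describe the sort.

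**Figure D1:**
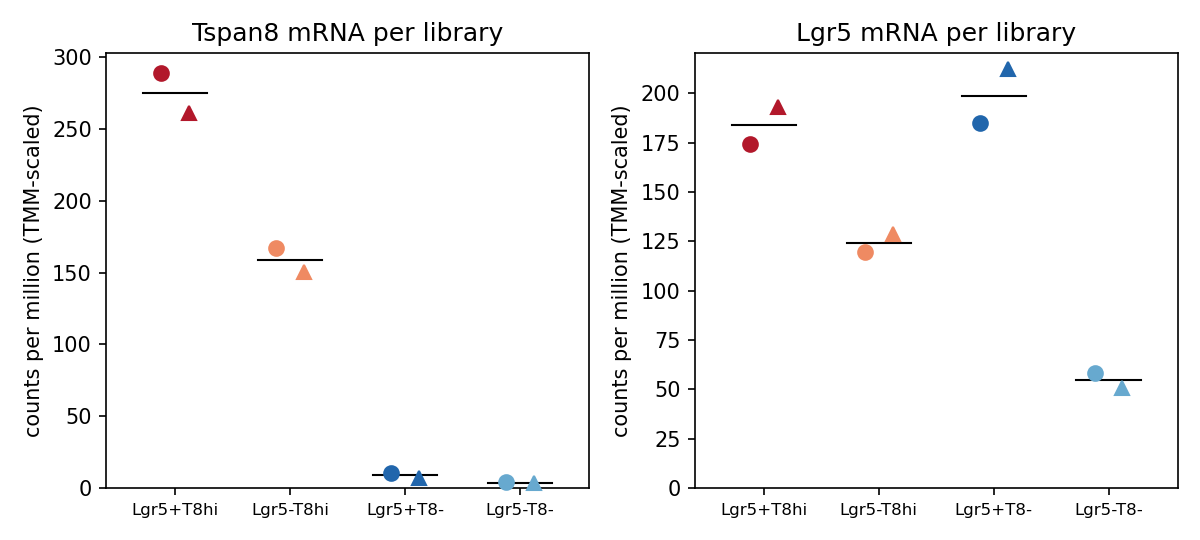
Tspan8 (left) and Lgr5 (right) mRNA in CPM for each library of the 4 sorted populations, with circles for batch 1, triangles for batch 2 and a horizontal line for the mean of 2 libraries. Tspan8 lay at 275 and 159 in the T8hi populations on average, and Lgr5 was lowest in Lgr5-T8- cells at 54.4.

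Replicates of a population correlated at r = 0.982 to 0.989 across genes, and libraries of different populations at 0.964 to 0.988 (genes are not independent replicates). The first 3 principal components held 35.3%, 22.7% and 19.3% of the variance. The 2 batches differed in 2649 genes higher and 2787 lower in batch 2, so batch was a block in the fits unless stated. Of 16526 genes tested, 1509 were higher and 912 lower with Tspan8, and 699 were higher and 803 lower with Lgr5. Across genes, the log2 fold changes of the 2 batches correlated at r = 0.693 for Tspan8, 0.566 for Lgr5 and 0.445 for their interaction.

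**Figure D2:**
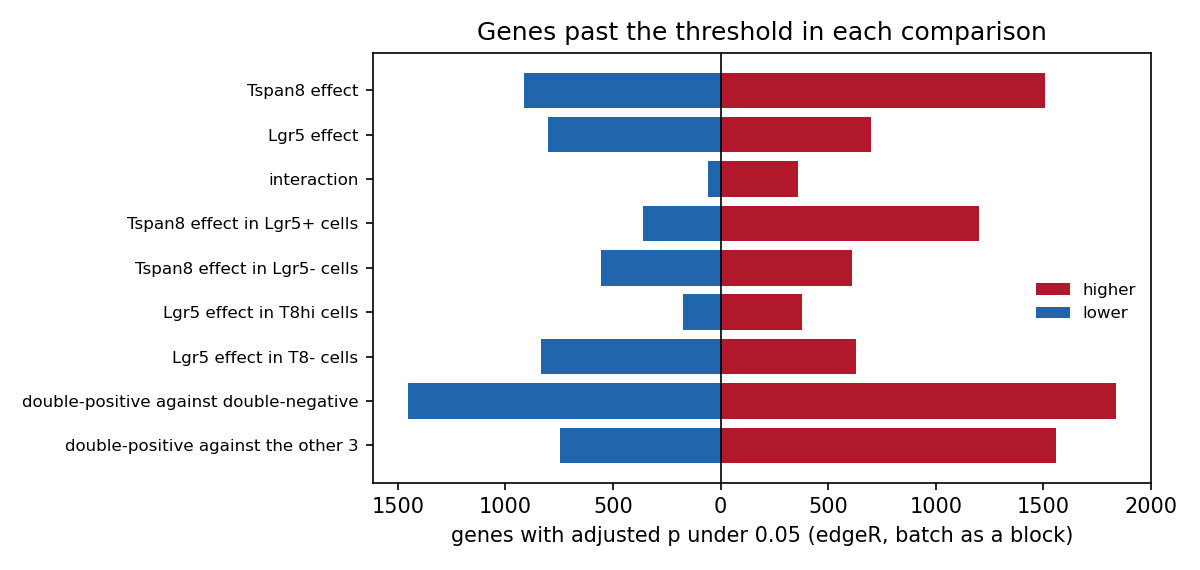
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with batch as a block, drawn to the right for genes that were higher and to the left for genes that were lower in the first-named population or with the named marker. The comparison of Lgr5+T8hi with Lgr5-T8- cells gave 1837 higher and 1450 lower genes, and the interaction 361 and 60.

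The first comparison was of T8hi with T8- cells, averaged over Lgr5 status. Among genes with a mean of at least 5 CPM, the milk protein gene Csn3 was among the most increased in the T8hi populations. Csn3 (Entrez 12994, chromosome 5, 87925579 to 87932550), which encodes kappa-casein, was higher by 2.31 ± 0.10 (edgeR adjusted p = 2.35e-07), with 38.2 ± 3.66 CPM in Lgr5+T8hi and 68.0 ± 18.8 in Lgr5-T8hi against 7.87 ± 3.30 in Lgr5+T8- and 13.7 ± 3.12 in Lgr5-T8- cells. Wfdc18, a whey acidic protein family member, rose by 2.52 ± 0.13, Btn1a1, a membrane protein of milk fat globules, by 1.99 ± 0.16, and Ocln, the tight junction protein occludin, by 2.01 ± 0.09 (edgeR adjusted p between 2.13e-07 and 7.75e-06). Thbs4 was higher by 2.41 ± 0.22, Cilp by 2.24 ± 0.41, Apod by 2.19 ± 0.18 and Col5a3 by 1.97 ± 0.23. Ifi205, one of a family of interferon-inducible genes with near-identical copies and therefore uncertain, was higher by 2.07 ± 0.14. The strongest decrease among genes with a mean of at least 5 CPM was in Eya1, a transcriptional cofactor (-2.41 ± 0.15). Serpinb2, which encodes a protease inhibitor, fell by 2.00 ± 0.49. Ryr3, a calcium release channel, was at -1.78 ± 0.14 and Kcnmb1, a potassium channel subunit of smooth muscle, at -1.61 ± 0.07. Trpm3 (-1.58 ± 0.27), Asb2 (-1.49 ± 0.11), Pappa2 (-1.45 ± 0.14), Igfbp2 (-1.42 ± 0.08) and Zfhx4 (-1.38 ± 0.12) followed. Serpinb2, Trpm3, Pappa2 and Zfhx4 stood apart in Lgr5-T8- cells, at 38.5 ± 11.3, 49.1 ± 1.27, 20.9 ± 6.63 and 41.3 ± 7.01 CPM on average, against at most 1.51, 12.6, 3.88 and 6.54 in the other populations. With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Cilp without Lgr5+T8- replicate 2 (0.0627), Lgr5-T8- replicate 1 (0.201) or Lgr5-T8- replicate 2 (0.128). Serpinb2 passed the threshold no more without Lgr5+T8- replicate 2 (0.161), Lgr5-T8- replicate 1 (0.0929) or Lgr5-T8- replicate 2 (0.0943). Trpm3 passed the threshold no more without Lgr5+T8hi replicate 1 (0.054), Lgr5-T8hi replicate 1 (0.139) or Lgr5-T8hi replicate 2 (0.136).

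Smooth-muscle contractile genes, which basal cells use to squeeze milk, were mostly lower in the T8hi populations. Of the list, 17 of 22 were lower and 1 higher (18 and 1 adjusted over the list alone), with a median -0.48, camera adjusted p = 4.58e-22, 0.0674 with an estimated correlation. Actg2 and Acta2, the smooth-muscle actins, fell by 1.31 ± 0.07 and 0.67 ± 0.07, and Myh11, smooth-muscle myosin, by 0.83 ± 0.07 (edgeR adjusted p between 1.13e-06 and 6.56e-05). Among basal epithelial markers, 7 of 20 were lower and 1 higher (9 and 1 adjusted over the list alone), with a median -0.15, camera adjusted p = 2.84e-04, 0.0851 with an estimated correlation. Trp63, the master regulator of basal cells, was at -0.41 ± 0.07 and Nrg1 at -0.62 ± 0.07. Among luminal progenitor and milk genes, 12 of 16 were higher and 1 lower (13 and 2 adjusted over the list alone), with a median 1.56, camera adjusted p = 4.83e-30, 0.0851 with an estimated correlation. Besides Csn3 and Wfdc18, Cd14 (1.59 ± 0.10) and the epithelial transcription factor Ehf (1.69 ± 0.12) rose. Hormone-sensing luminal genes gave 9 higher and 0 lower of 17 (12 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 1.17e-09, 0.0952 with an estimated correlation), led by Foxa1, a cofactor of the oestrogen receptor (1.59 ± 0.12), with mean levels highest in the Lgr5+T8hi libraries (0.40 and 0.64). Pan-luminal genes gave 7 higher and 0 lower of 15 (8 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 8.83e-08, 0.0952 with an estimated correlation), with Muc1 at 0.89 ± 0.08 and Cldn7 at 1.75 ± 0.16.

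Markers of cell types other than mammary epithelium were higher on average over the T8hi populations, but not evenly. Mean endothelial, immune, erythroid, fibroblast, pericyte and adipocyte levels (log2 CPM centred on each gene) were highest in the Lgr5+T8hi libraries. In Lgr5-T8hi replicate 1 the endothelial and erythroid levels were -0.65 and -0.56, below the -0.22 and -0.10 of Lgr5-T8- replicate 1. Fibroblast genes gave 13 higher and 0 lower of 15 (14 and 0 adjusted over the list alone, median 1.34, camera adjusted p = 2.05e-34, 0.0851 with an estimated correlation), with the collagen gene Col1a2 at 1.56 ± 0.09 and Dpt at 1.81 ± 0.11. Endothelial genes gave 7 higher and 0 lower of 15 (12 and 0 adjusted over the list alone, median 1.07, camera adjusted p = 3.42e-09, 0.312 with an estimated correlation), with 11 and 0 by DESeq2 and 10 and 0 by limma-voom and Cd34 at 0.81 ± 0.10. Pericyte genes gave 8 higher and 0 lower of 10 (8 and 0 adjusted over the list alone, median 0.87, camera adjusted p = 5.08e-08, 0.0851 with an estimated correlation), with the receptor Notch3 at 1.06 ± 0.09. Immune cell genes gave 10 higher and 0 lower of 16 (11 and 0 adjusted over the list alone, median 1.19, camera adjusted p = 1.17e-09, 0.164 with an estimated correlation), with Ptprc, which encodes the leukocyte antigen CD45, at 1.66 ± 0.18. Schwann and glial genes gave 4 higher and 0 lower of 10 (6 and 0 adjusted over the list alone, median 0.89, camera adjusted p = 2.21e-05, 0.25 with an estimated correlation), with the myelin gene Mbp at 0.61 ± 0.07. Adipocyte genes gave 4 higher and 1 lower of 7 (4 and 1 adjusted over the list alone, median 1.24, camera adjusted p = 5.43e-05, 0.0851 with an estimated correlation), with Lpl, lipoprotein lipase, at 1.43 ± 0.10. The 1 lower member was Lep, which encodes leptin, at -1.69 ± 0.20. Erythroid genes gave 3 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, median 1.45, camera adjusted p = 7.50e-05, 0.19 with an estimated correlation). Of their members, 1 had 1 CPM or more in every population. Besides Alas2 they are globin genes with near-identical copies, so their values are uncertain, Hbb-b1 being at 1.66 ± 0.24. Epidermal keratinocyte genes went both ways, 4 higher and 3 lower of 18 (4 and 3 adjusted over the list alone, median 0.05, mean -0.01, camera adjusted p = 0.513), and their median was 0.29 in batch 1 and -0.14 in batch 2. Leaving out 1 library moved list medians by over 1.5 times, to 2.22 without Lgr5+T8- replicate 1 for erythroid genes.

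Matrix, signalling and defence genes followed. Extracellular matrix remodelling genes gave 15 higher and 3 lower of 29 (15 and 3 adjusted over the list alone, median 0.45, camera adjusted p = 3.12e-14, 0.0851 with an estimated correlation), with the protease genes Mmp3 at 1.68 ± 0.13 and Adamts5 at 1.00 ± 0.07. Basement membrane genes went the other way, with 3 higher and 9 lower of 25 (3 and 10 adjusted over the list alone, median -0.14, camera adjusted p = 0.00363, 0.505 with an estimated correlation). The laminin gene Lama1 was at -1.29 ± 0.08 and Col4a1 at -0.75 ± 0.07, while Nid2 was at 1.15 ± 0.09. Interferon-stimulated genes gave 12 higher and 0 lower of 25 (13 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 1.08e-08, 0.0851 with an estimated correlation), with Cxcl10 at 1.19 ± 0.09. Chemokines, cytokines and receptors gave 9 higher and 1 lower of 28 (12 and 3 adjusted over the list alone, median 0.32, camera adjusted p = 8.83e-08, 0.0851 with an estimated correlation), with the cytokine genes Il33 at 1.56 ± 0.13 and Cxcl2 at 0.84 ± 0.07. Reported mammary stem cell markers gave 8 higher and 3 lower of 20 (10 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 2.84e-04, 0.0851 with an estimated correlation), with Foxc1 at 1.48 ± 0.10, Nrp1 at 1.11 ± 0.08 and the protein C receptor gene Procr at 0.86 ± 0.07. The stem cell list shares the endothelial marker Cdh5 with the endothelial list. Epithelial-mesenchymal transition factors, of which Foxc1 is also one, gave 7 higher and 1 lower of 16 (7 and 3 adjusted over the list alone, median 0.40, camera adjusted p = 4.58e-06, 0.0952 with an estimated correlation). TGF-beta and BMP pathway genes gave 10 higher and 2 lower of 32 (11 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.00285, 0.0952 with an estimated correlation), with Bmp2 at 0.90 ± 0.11. Wnt pathway genes went both ways, 7 higher and 6 lower of 40 (8 and 11 adjusted over the list alone, median 0.01, camera adjusted p = 0.268), with the secreted inhibitors Sfrp1 at 1.61 ± 0.07 and Sfrp2 at 1.22 ± 0.08 and the ligand Wnt6 at -1.25 ± 0.12. Tetraspanin genes other than Tspan8 gave 7 higher and 3 lower of 23 (9 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.00374, 0.345 with an estimated correlation). Notch pathway genes gave 6 higher and 2 lower of 20 (7 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.0834) and neuronal guidance genes 7 higher and 7 lower of 34 (9 and 8 adjusted over the list alone, median -0.08, camera adjusted p = 0.839), so neither passed as a list. Notch1 was at 0.62 ± 0.08 and the guidance gene Ntn1 at 1.56 ± 0.09. In Lgr5+T8hi replicates 1 and 2, the libraries where endothelial and fibroblast genes were highest, mean levels were 0.49 and 0.29 for the matrix list, 0.46 and 0.33 for interferon-stimulated genes, 0.46 and 0.32 for the chemokine list and 0.32 and 0.19 for the stem cell list. They were 0.36 and 0.30 for epithelial-mesenchymal transition factors, 0.25 and 0.25 for the tetraspanin list and 0.12 and 0.21 for the Notch list, and each of these 7 lists was lower in the other 6 libraries. Some medians moved by over 1.5 times when 1 library was left out, to -0.04 without Lgr5+T8- replicate 2, -0.03 without Lgr5-T8- replicate 1 and -0.21 without Lgr5-T8- replicate 2 for basement membrane genes. For interferon-stimulated genes it was 0.32 without Lgr5+T8hi replicate 2, 0.34 without Lgr5+T8- replicate 2 and 0.35 without Lgr5-T8- replicate 1. Without Lgr5+T8- replicate 1 it was 0.17 for stem cell markers and 0.24 for TGF-beta and BMP genes. For epithelial-mesenchymal transition factors it was 0.62 without that library or Lgr5-T8- replicate 2. For tetraspanin genes it was 0.19 without Lgr5+T8hi replicate 2.

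Proliferation genes were lower as a list in the T8hi populations, with 0 higher and 9 lower of 40 (0 and 10 adjusted over the list alone, median -0.47, camera adjusted p = 1.27e-06, 0.505 with an estimated correlation), with 0 higher and 22 lower at an unadjusted p under 0.05, 0 and 15 by DESeq2 and 0 and 7 by limma-voom. Their median was -0.34 in batch 1 and -0.62 in batch 2, and the number that were lower went from 0 without Lgr5+T8hi replicate 2 and 1 without Lgr5+T8- replicate 2 to 17 without Lgr5-T8- replicate 2 and 28 without Lgr5+T8- replicate 1. Cell-cycle inhibitor and quiescence genes gave 0 higher and 0 lower of 19 (3 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.565), with 5 higher and 3 lower at an unadjusted p under 0.05, 4 and 0 by DESeq2 and 0 and 0 by limma-voom. The ribosomal list gave 0 higher and 0 lower of 82 (0 and 0 adjusted over the list alone, median 0.01, camera adjusted p = 0.909), with 1 higher and 0 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2 and 0 and 0 by limma-voom. Its median was 0.10 in batch 1 and -0.06 in batch 2. Cholesterol synthesis genes gave 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.12), with 0 higher and 3 lower at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 0 and 0 by limma-voom. Oxidative phosphorylation genes gave 0 higher and 0 lower of 71 (0 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.00196, 0.684 with an estimated correlation), with 0 higher and 15 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2 and 0 and 0 by limma-voom. Hormone and growth factor receptors gave 7 higher and 2 lower of 27 (9 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.0456, 0.505 with an estimated correlation), with Pdgfra at 0.87 ± 0.10. Immediate-early and dissociation stress genes gave 5 higher and 0 lower of 32 (5 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 0.00439, 0.658 with an estimated correlation), with Klf6 at 0.46 ± 0.08. HOX and positional transcription factors gave 8 higher and 2 lower of 27 (12 and 3 adjusted over the list alone, median 0.34, camera adjusted p = 0.0496, 0.505 with an estimated correlation), with 4 and 2 by DESeq2 and 7 and 2 by limma-voom and Tbx2 at -1.27 ± 0.09. The mean level of this list was also highest in the Lgr5+T8hi libraries, at 0.28 and 0.46, against -0.09 and 0.10 in Lgr5-T8hi and -0.14 and 0.08 in Lgr5-T8-. Replication-dependent histone genes gave 1 higher and 0 lower of 22 (1 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.229). Hormone and growth factor receptors lost their camera call without the batch block (adjusted p = 0.0676), without Lgr5+T8hi replicate 2 (adjusted p = 0.143), without Lgr5-T8hi replicate 1 (adjusted p = 0.134) or without Lgr5-T8- replicate 2 (adjusted p = 0.161). Immediate-early and dissociation stress genes lost their camera call without Lgr5+T8- replicate 2 (adjusted p = 0.194) or without Lgr5-T8- replicate 1 (adjusted p = 0.161). HOX and positional transcription factors lost their camera call with RLE normalization (adjusted p = 0.0508), without Lgr5+T8hi replicate 2 (adjusted p = 0.0676), without Lgr5-T8hi replicate 2 (adjusted p = 0.0628), without Lgr5+T8- replicate 2 (adjusted p = 0.305) or without Lgr5-T8- replicate 1 (adjusted p = 0.284). Oxidative phosphorylation genes lost their camera call without Lgr5+T8hi replicate 2 (adjusted p = 0.134) or without Lgr5-T8- replicate 2 (adjusted p = 0.168). Medians that moved by over 1.5 times with 1 library left out changed, to -0.25 without Lgr5+T8- replicate 2 for proliferation genes. For oxidative phosphorylation genes it was -0.06 without Lgr5+T8hi replicate 2, -0.07 without Lgr5+T8- replicate 1 and -0.05 without Lgr5-T8- replicate 2. For hormone and growth factor receptors it was 0.12 without Lgr5+T8hi replicate 1, 0.04 without Lgr5+T8hi replicate 2, 0.11 without Lgr5+T8- replicate 2 and 0.13 without Lgr5-T8- replicate 1. For immediate-early and dissociation stress genes it was 0.30 without Lgr5+T8- replicate 1, 0.07 without Lgr5+T8- replicate 2, 0.07 without Lgr5-T8- replicate 1 and 0.29 without Lgr5-T8- replicate 2. For HOX and positional transcription factors it was 0.21 without Lgr5+T8- replicate 2.

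Under camera with a preset correlation of 0.01, 25 of 33 lists passed for Tspan8, fry called 18, and with an estimated correlation camera called 0 (14 at an unadjusted p under 0.05). Without the batch block, 705 genes passed (550 higher and 155 lower). Against 1509 higher and 912 lower with all libraries, the total was 1576 (1117 higher, 459 lower) without Lgr5+T8hi replicate 1, 1426 (950 higher, 476 lower) without Lgr5+T8hi replicate 2 and 1609 (1127 higher, 482 lower) without Lgr5-T8hi replicate 1. It was 1709 (1204 higher, 505 lower) without Lgr5-T8hi replicate 2, 1650 (1110 higher, 540 lower) without Lgr5+T8- replicate 2 and 3353 (1724 higher, 1629 lower) without Lgr5-T8- replicate 2. Named genes no longer called without the block, with that adjusted p, were Adamts5 (0.123), Bmp2 (0.123), Ifi205 (0.0777), Klf6 (0.135), Notch1 (0.0522), Nrg1 (0.595), Procr (0.537), Serpinb2 (0.0575), Trp63 (0.276), Trpm3 (0.0523) and Wnt6 (0.164).

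**Figure D3:**
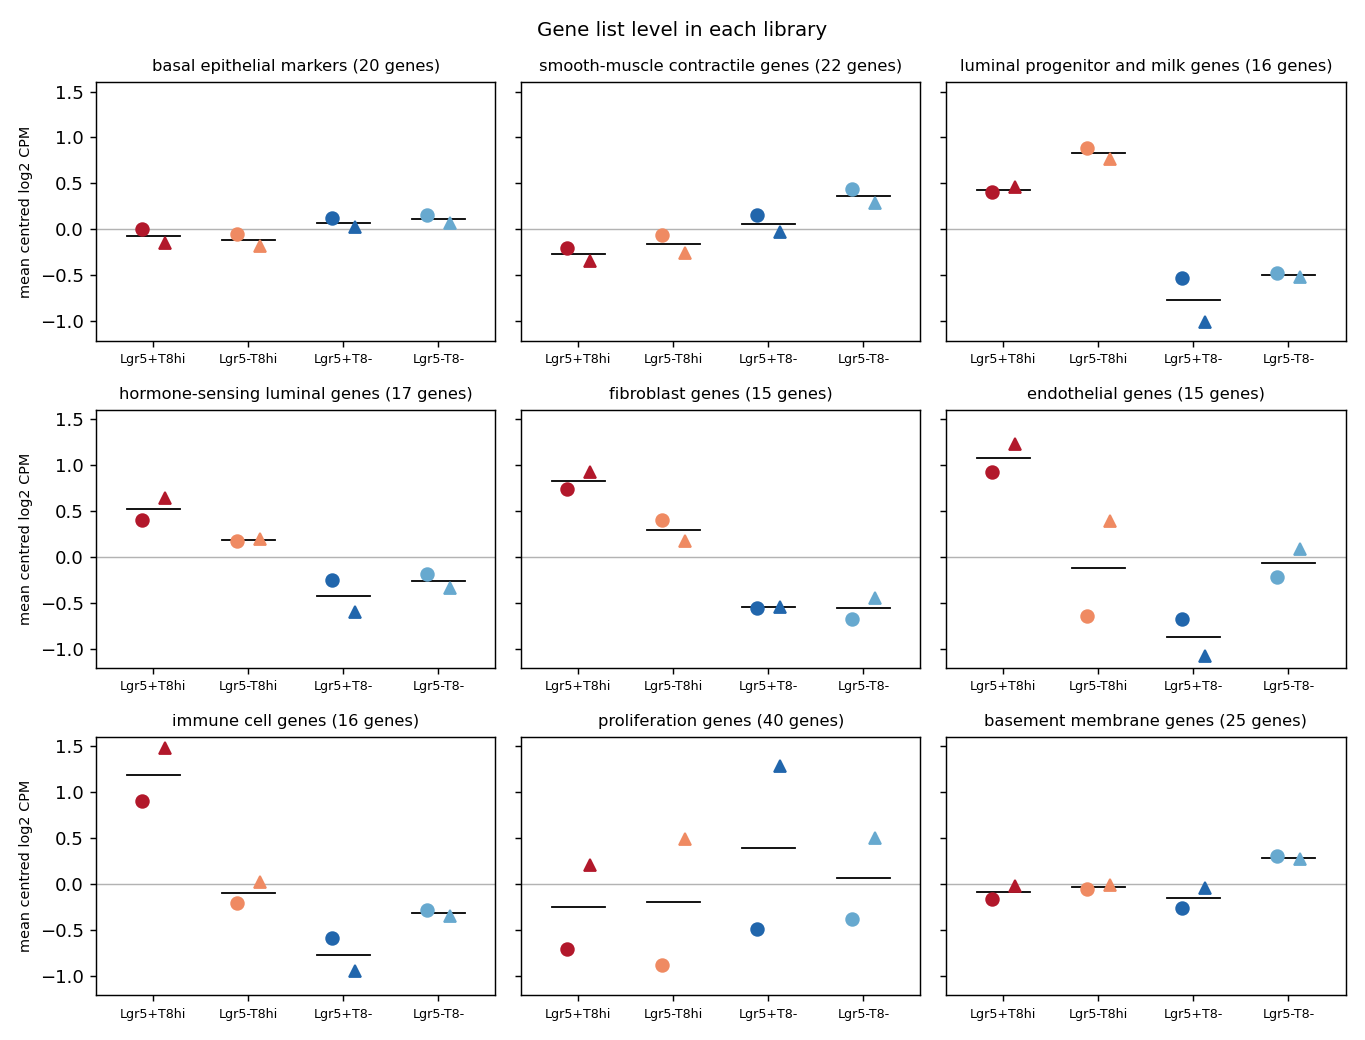
Level of 9 gene lists in each library, as the mean over list members of the log2 CPM centred on each gene's mean over the 8 libraries, with circles for batch 1, triangles for batch 2 and lines for the mean of 2 libraries. The immune list stood at 0.90 and 1.47 in the Lgr5+T8hi libraries, and the proliferation list at 1.28 in Lgr5+T8- replicate 2.

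The second comparison asked how Lgr5+ basal cells differ from Lgr5- cells, averaged over both levels of Tspan8. The secreted Wnt inhibitor Sfrp1 (Entrez 20377, chromosome 8, 23411383 to 23449632) rose by 1.87 ± 0.08 (edgeR adjusted p = 2.17e-07), from 34.2 ± 11.8 CPM in Lgr5-T8- and 151 ± 36.2 in Lgr5-T8hi to 182 ± 53.3 in Lgr5+T8- and 373 ± 64.8 in Lgr5+T8hi cells. Frmpd4, a scaffold protein gene, was higher by 2.47 ± 0.15, Mfap5, a microfibril component, by 1.64 ± 0.14, and Ocln by 1.52 ± 0.09. Gli1, a transcription factor of the Hedgehog pathway, was higher by 1.43 ± 0.19, and the abundant protease inhibitor Slpi by 1.35 ± 0.07. Ptprd (1.40 ± 0.11), the myosin gene Myo5b (1.26 ± 0.09) and the somatostatin receptor gene Sstr1 (1.23 ± 0.09) also rose. Among genes lower in Lgr5+ cells were Serpinb2 (-4.39 ± 0.35), the voltage-gated potassium channel genes Kcna2 (-3.43 ± 0.40) and Kcna1 (-2.21 ± 0.37), Coch (-3.35 ± 0.21), the collagen gene Col9a1 (-2.82 ± 0.16) and Trpm3 (-2.56 ± 0.27). Ptprt (-2.53 ± 0.16), Adam11 (-2.03 ± 0.25), Zfhx4 (-1.91 ± 0.12) and Dio2, a thyroid hormone deiodinase (-1.80 ± 0.13), were lower too (edgeR adjusted p between 1.12e-06 and 0.0235 for the genes after Sfrp1). With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Kcna1 without Lgr5-T8- replicate 1 (0.0819) or Lgr5-T8- replicate 2 (0.0997). Trpm3 passed the threshold no more without Lgr5-T8hi replicate 1 (0.0684) or Lgr5-T8hi replicate 2 (0.0553).

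Basement membrane genes were lower on average in Lgr5+ cells, with 2 higher and 8 lower of 25 (3 and 9 adjusted over the list alone, median -0.12, camera adjusted p = 3.49e-05, 0.672 with an estimated correlation). Lama1 was at -1.53 ± 0.08 and Col4a1 at -0.73 ± 0.07. The difference lay mainly within T8- cells, with 1 higher and 8 lower (median -0.25), against 1 and 1 within T8hi cells (median -0.05). The mean level of this list was 0.30 and 0.27 in the Lgr5-T8- libraries and below 0 in every other library. Neuronal guidance genes gave 4 higher and 10 lower of 34 (6 and 12 adjusted over the list alone, median -0.14, camera adjusted p = 0.00131, 0.672 with an estimated correlation), with Sema3d at -1.71 ± 0.10 and Slit2 at -1.18 ± 0.08 but the netrin gene Ntn4 at 1.01 ± 0.07. Contractile genes gave 2 higher and 7 lower of 22 (2 and 9 adjusted over the list alone, median -0.14, camera adjusted p = 0.00167, 0.672 with an estimated correlation), with Kcnmb1 at -0.59 ± 0.07 and the smooth-muscle cofactor Myocd at -1.29 ± 0.18. Luminal progenitor and milk genes were lower, with 1 higher and 8 lower of 16 (2 and 9 adjusted over the list alone, median -0.48, camera adjusted p = 2.63e-04, 0.672 with an estimated correlation), among them Trf, which encodes transferrin, at -0.84 ± 0.08 and Csn3 at -0.81 ± 0.10. Pan-luminal genes were higher, with 5 higher and 0 lower of 15 (8 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 4.53e-04, 0.672 with an estimated correlation), Muc1 being at 0.62 ± 0.08 and the keratin gene Krt18 at 0.48 ± 0.10. Extracellular matrix remodelling genes gave 9 higher and 3 lower of 29 (9 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 4.35e-04, 0.672 with an estimated correlation), with Adamts5 at 1.03 ± 0.07 and Adamts1 at 0.86 ± 0.07. Fibroblast genes gave 7 higher and 2 lower of 15 (8 and 2 adjusted over the list alone, median 0.41, camera adjusted p = 5.53e-04, 0.672 with an estimated correlation), with Fbln1 at 0.61 ± 0.07 and Dcn at -0.96 ± 0.11. Schwann and glial genes gave 0 higher and 4 lower of 10 (0 and 6 adjusted over the list alone, median -0.72, camera adjusted p = 2.63e-04, 0.672 with an estimated correlation), with the adhesion molecule L1cam at -1.72 ± 0.27. Immune cell genes gave 1 higher and 0 lower of 16 (3 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 0.0253, 0.824 with an estimated correlation). Endothelial genes gave 0 higher and 0 lower of 15 (0 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 0.294) and had medians of 0.60 in batch 1 and -0.21 in batch 2, with 2 higher and 0 lower at an unadjusted p under 0.05, 1 and 0 by DESeq2 and 0 and 0 by limma-voom. Wnt pathway genes gave 4 higher and 7 lower of 40 (6 and 10 adjusted over the list alone, median 0.00, camera adjusted p = 0.379) and did not pass as a list, although Sfrp2 was at 0.97 ± 0.08 and the ligand gene Wnt11 at 0.81 ± 0.07. Luminal progenitor and milk genes lost their camera call without Lgr5+T8- replicate 2 (adjusted p = 0.0617). Immune cell genes lost their camera call without Lgr5+T8hi replicate 2 (adjusted p = 0.227), without Lgr5+T8- replicate 1 (adjusted p = 0.356) or without Lgr5-T8- replicate 2 (adjusted p = 0.0724). Leaving out 1 library moved list medians by over 1.5 times, to 0.13 without Lgr5+T8- replicate 1 for pan-luminal genes. For fibroblast genes it was 0.26 without Lgr5-T8hi replicate 2. For immune cell genes it was 0.65 without Lgr5+T8- replicate 2. With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Krt18 without Lgr5+T8hi replicate 2 (0.0745) or Lgr5-T8- replicate 1 (0.0924).

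For Lgr5, 9 of 33 lists passed camera with the preset correlation, 2 passed fry and 0 passed camera with an estimated correlation (1 at an unadjusted p under 0.05). The count of 1502 genes fell to 219 without the batch block (89 higher and 130 lower). It was 720 (360 higher, 360 lower) without Lgr5+T8hi replicate 1, 897 (395 higher, 502 lower) without Lgr5+T8hi replicate 2 and 814 (377 higher, 437 lower) without Lgr5-T8hi replicate 1. The count was 889 (403 higher, 486 lower) without Lgr5+T8- replicate 1 and 2596 (1193 higher, 1403 lower) without Lgr5-T8- replicate 2. Named genes no longer called without the block, with that adjusted p, were Adamts5 (0.209), Csn3 (0.158), Fbln1 (0.194), Krt18 (0.593), Muc1 (0.214), Myocd (0.138), Ocln (0.0511), Ptprd (0.0695) and Sstr1 (0.235).

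Whether the Tspan8 effect differs with Lgr5 status was tested by the interaction, the effect in Lgr5+ cells minus that in Lgr5- cells. It passed for 361 genes with a higher and 60 with a lower difference. The most positive were Serpinb2 (5.41 ± 0.88), Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (3.43 ± 0.37), and Pappa2, a protease of insulin-like growth factor binding proteins (2.90 ± 0.29; edgeR adjusted p = 0.0268, 0.00967 and 6.61e-04). Lars2 was at 992 ± 277 CPM in Lgr5-T8- cells and at 119 to 174 in the other populations. With the same bound, the most negative were Frmpd4 (-1.63 ± 0.30), Adamts6 (-1.57 ± 0.26) and Esyt3 (-1.52 ± 0.20). Endothelial genes gave 4 higher and 0 lower of 15 (14 and 0 adjusted over the list alone, median 1.91, camera adjusted p = 1.24e-27, 0.188 with an estimated correlation), with 8 and 0 by DESeq2 and 6 and 0 by limma-voom and Cd34 at 1.89 ± 0.20. Immune cell genes gave 6 higher and 0 lower of 16 (11 and 0 adjusted over the list alone, median 1.96, camera adjusted p = 6.81e-15, 0.188 with an estimated correlation), with Ptprc at 2.12 ± 0.36, and erythroid genes 3 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, median 3.73, camera adjusted p = 1.82e-14, 0.174 with an estimated correlation). Basement membrane genes gave 3 higher and 0 lower of 25 (9 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 1.91e-06, 0.374 with an estimated correlation), with 6 and 0 by DESeq2 and 3 and 0 by limma-voom and Col4a1 at 0.83 ± 0.15. Nrp1, a receptor of semaphorins and vascular growth factors, was at 2.25 ± 0.16. Proliferation genes gave 0 higher and 0 lower of 40 (0 and 0 adjusted over the list alone, median -0.45, camera adjusted p = 2.59e-05, 0.589 with an estimated correlation), and their median was 0.25 in batch 1 and -1.16 in batch 2, with 0 higher and 8 lower at an unadjusted p under 0.05, 0 and 0 by DESeq2 and 0 and 0 by limma-voom. Sfrp1 was at -1.10 ± 0.15. Proliferation genes lost their camera call without Lgr5+T8- replicate 2 (adjusted p = 0.305) or without Lgr5-T8- replicate 2 (adjusted p = 0.055). Some medians moved by over 1.5 times when 1 library was left out, to -0.20 without Lgr5+T8hi replicate 2, -0.79 without Lgr5+T8- replicate 1, -0.11 without Lgr5+T8- replicate 2, -0.74 without Lgr5-T8- replicate 1 and -0.28 without Lgr5-T8- replicate 2 for proliferation genes. With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Serpinb2 without Lgr5+T8hi replicate 2 (0.1), Lgr5-T8- replicate 1 (0.0786) or Lgr5-T8- replicate 2 (0.0926). Lars2 passed the threshold no more without Lgr5-T8- replicate 1 (0.201) or Lgr5-T8- replicate 2 (0.154). Frmpd4 passed the threshold no more without Lgr5+T8hi replicate 1 (0.083), Lgr5-T8hi replicate 1 (0.0524) or Lgr5+T8- replicate 1 (0.0889). Adamts6 passed the threshold no more without Lgr5+T8hi replicate 1 (0.0951) or Lgr5+T8hi replicate 2 (0.0519). Col4a1 passed the threshold no more without Lgr5+T8hi replicate 1 (0.0739), Lgr5+T8hi replicate 2 (0.0895), Lgr5-T8hi replicate 1 (0.079) or Lgr5-T8hi replicate 2 (0.0532). Ptprc passed the threshold no more without Lgr5+T8hi replicate 2 (0.0849) or Lgr5+T8- replicate 2 (0.0568).

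For the interaction, 22 of 33 lists passed camera with the preset correlation, 6 passed fry and 0 passed with an estimated correlation (8 at an unadjusted p under 0.05). Without the batch block the interaction passed for 1 gene, Il1r2, an interleukin-1 decoy receptor of the chemokine list (4.43 ± 0.34, edgeR adjusted p = 9.49e-05 with the block and 0.0173 without it). The named genes not called without the block, with that adjusted p, were Adamts6 (0.217), Cd34 (0.125), Col4a1 (0.387), Esyt3 (0.137), Frmpd4 (0.817), Lars2 (0.0779), Lgr5 (0.125), Nrp1 (0.0779), Pappa2 (0.193), Ptprc (0.151), Serpinb2 (0.126) and Sfrp1 (0.708). Against 361 higher and 60 lower with all libraries, the count was 129 (115 higher, 14 lower) without Lgr5+T8hi replicate 1, 110 (98 higher, 12 lower) without Lgr5+T8hi replicate 2 and 302 (280 higher, 22 lower) without Lgr5-T8hi replicate 1. The total became 361 (328 higher, 33 lower) without Lgr5-T8hi replicate 2, 192 (166 higher, 26 lower) without Lgr5+T8- replicate 2 and 417 (309 higher, 108 lower) without Lgr5-T8- replicate 1. The total became 570 (418 higher, 152 lower) without Lgr5-T8- replicate 2.

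Within Lgr5+ cells, Tspan8 separated 1201 higher and 359 lower genes. Sema3g, a secreted semaphorin, was higher by 2.73 ± 0.22 and the growth factor gene Igf2 by 2.55 ± 0.30, while Eya1 (-2.09 ± 0.24), Ryr3 (-1.93 ± 0.20) and Kcnmb1 (-1.62 ± 0.10) were lower. Within Lgr5- cells 611 were higher and 556 lower. Among those with a mean of at least 5 CPM, Wfdc18 (3.05 ± 0.19) and Ocln (2.77 ± 0.14) led one side. Serpinb2 (-4.70 ± 0.34), Lars2 (-2.95 ± 0.27) and Pappa2 (-2.90 ± 0.19) led the other. Between these comparisons, which share no library, 293 genes were higher in both (44.4 if the lists were independent), 183 lower in both (12.1) and 21 opposite. Across genes the 2 effects correlated at r = 0.314 (rho = 0.407), or r = 0.478 over genes with at least 1 CPM in 4 libraries. Within T8hi cells, Lgr5 separated 379 higher and 173 lower genes. Frmpd4 (1.66 ± 0.19), the endothelial sialomucin gene Emcn (1.56 ± 0.25) and C1qtnf9 (1.47 ± 0.24) led one side, and Adam11 (-3.00 ± 0.35), Coch (-2.98 ± 0.28) and Kcna2 (-2.77 ± 0.47) the other. Within T8- cells 630 were higher and 834 lower, with Frmpd4 (3.28 ± 0.23), Sfrp1 (2.42 ± 0.11) and Ocln (2.28 ± 0.14) against Serpinb2 (-7.09 ± 0.45), Kcna2 (-4.09 ± 0.66) and Col9a1 (-3.96 ± 0.23). The Lgr5 effects at the 2 levels of Tspan8 correlated at r = 0.165 (rho = 0.271) across genes, or 0.275 with the stricter filter and 0.034 without Lgr5+T8- replicate 1 and 0.0861 without Lgr5-T8hi replicate 1. They had 125 genes higher in both (14.4 if independent), 121 lower in both (8.73) and 40 opposite.

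In these 4 fits the batch block and single libraries moved the counts. Without the block, the totals were 512 in Lgr5+ cells (484 higher), 147 in Lgr5- cells, 0 in T8hi cells and 208 in T8- cells (64 higher). For the 0 in T8hi cells, edgeR gave 1094 genes at an unadjusted p under 0.05, and limma-voom without the block called 0. The Tspan8 count in Lgr5+ cells was 796 (712 higher, 84 lower) without Lgr5+T8hi replicate 1, 614 (532 higher, 82 lower) without Lgr5+T8hi replicate 2 and 744 (641 higher, 103 lower) without Lgr5+T8- replicate 2. This count was 1995 (1449 higher, 546 lower) without Lgr5-T8- replicate 1 and 2088 (1391 higher, 697 lower) without Lgr5-T8- replicate 2. In Lgr5- cells it was 546 (306 higher, 240 lower) without Lgr5-T8hi replicate 1, 592 (355 higher, 237 lower) without Lgr5-T8hi replicate 2 and 1927 (911 higher, 1016 lower) without Lgr5-T8- replicate 2. The Lgr5 count in T8hi cells was 39 (29 higher, 10 lower) without Lgr5+T8hi replicate 1, 47 (23 higher, 24 lower) without Lgr5+T8hi replicate 2 and 104 (66 higher, 38 lower) without Lgr5-T8hi replicate 1. It came to 365 (241 higher, 124 lower) without Lgr5-T8hi replicate 2, 924 (595 higher, 329 lower) without Lgr5-T8- replicate 1 and 931 (579 higher, 352 lower) without Lgr5-T8- replicate 2. In T8- cells it was 741 (288 higher, 453 lower) without Lgr5+T8- replicate 1, 972 (412 higher, 560 lower) without Lgr5+T8- replicate 2 and 2309 (1033 higher, 1276 lower) without Lgr5-T8- replicate 2. In T8hi cells the calls lost without the block, with that adjusted p, were Frmpd4 (0.409), Emcn (0.197), C1qtnf9 (0.273), Adam11 (0.179), Coch (0.179) and Kcna2 (0.179). With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Emcn without Lgr5+T8hi replicate 1 (0.196), Lgr5+T8hi replicate 2 (0.157), Lgr5-T8- replicate 1 (0.0902) or Lgr5-T8- replicate 2 (0.0804). C1qtnf9 passed the threshold no more without Lgr5+T8hi replicate 1 (0.179), Lgr5+T8hi replicate 2 (0.0886) or Lgr5-T8hi replicate 1 (0.0569). Adam11 passed the threshold no more without Lgr5+T8hi replicate 1 (0.0756). Coch passed the threshold no more without Lgr5+T8hi replicate 1 (0.0583) or Lgr5+T8hi replicate 2 (0.0617). Kcna2 passed the threshold no more without Lgr5+T8hi replicate 1 (0.287) or Lgr5+T8hi replicate 2 (0.24). In Lgr5- cells the same held for Lars2 without Lgr5-T8- replicate 1 (0.132) or Lgr5-T8- replicate 2 (0.0695), and in T8- cells for Kcna2 without Lgr5+T8- replicate 1 (0.093) or Lgr5+T8- replicate 2 (0.0696). Without the block, Sema3g (0.0511) and Ryr3 (0.064) were not called in Lgr5+ cells.

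Cells with both markers were set against the other 3 populations. Besides Tspan8, genes of blood vessels were among the largest increases. Sele and Selp, adhesion molecules of activated endothelium, were higher by 1.99 ± 0.27 and 1.94 ± 0.37, and Fabp4, a fatty acid carrier of adipocytes and capillaries, by 1.89 ± 0.21. Sfrp1 (1.95 ± 0.08), Gli1 (1.92 ± 0.19), Frmpd4 (2.02 ± 0.15), C1qtnf9 (1.99 ± 0.19) and Ifi205 (2.05 ± 0.14) rose alongside. Selp stood at 325 ± 112 CPM in Lgr5+T8hi cells and at 134 ± 57.0, 67.6 ± 29.0 and 63.1 ± 9.16 in Lgr5-T8hi, Lgr5+T8- and Lgr5-T8- cells. The genes that were most reduced were Eya1 (-2.47 ± 0.21), Trpm3 (-2.46 ± 0.37), Serpinb2 (-2.45 ± 0.51), Ptprt (-2.05 ± 0.20), Coch (-1.90 ± 0.27) and Col9a1 (-1.84 ± 0.20). Upk1b, a uroplakin (-1.84 ± 0.16), Lama1 (-1.69 ± 0.10), St8sia6 (-1.62 ± 0.24) and Col6a4 (-1.59 ± 0.10) were also lower (edgeR adjusted p at most 0.0419 for these genes). Endothelial genes gave 13 higher and 0 lower of 15 (15 and 0 adjusted over the list alone, median 1.47, camera adjusted p = 5.95e-18, 0.175 with an estimated correlation). Immune cell genes gave 12 higher and 0 lower of 16 (15 and 0 adjusted over the list alone, median 1.72, camera adjusted p = 2.32e-19, 0.0932 with an estimated correlation), with Ptprc at 2.23 ± 0.17. Fibroblast genes gave 14 higher and 0 lower of 15 (14 and 0 adjusted over the list alone, median 1.40, camera adjusted p = 3.09e-31, 0.0804 with an estimated correlation), with Dpt at 1.78 ± 0.11. Erythroid genes gave 4 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, median 2.36, camera adjusted p = 2.18e-10, 0.104 with an estimated correlation). Pericyte genes gave 8 higher and 0 lower of 10 (9 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 2.90e-07, 0.0804 with an estimated correlation). Contractile genes were again lower, with 1 higher and 12 lower of 22 (1 and 15 adjusted over the list alone, median -0.37, camera adjusted p = 1.47e-10, 0.0804 with an estimated correlation), and hormone-sensing luminal genes higher, with 9 higher and 2 lower of 17 (11 and 2 adjusted over the list alone, median 0.65, camera adjusted p = 1.20e-07, 0.154 with an estimated correlation), Foxa1 being at 1.69 ± 0.12. Medians that moved by over 1.5 times with 1 library left out changed, to 1.00 without Lgr5+T8hi replicate 1 and 0.35 without Lgr5+T8hi replicate 2 for hormone-sensing luminal genes. With a library left out, edgeR's adjusted p (in brackets) rose above the threshold for Sele without Lgr5+T8hi replicate 1 (0.066), Lgr5-T8- replicate 1 (0.136) or Lgr5-T8- replicate 2 (0.0987). Selp passed the threshold no more without Lgr5+T8hi replicate 1 (0.237), Lgr5+T8hi replicate 2 (0.158), Lgr5+T8- replicate 2 (0.0674), Lgr5-T8- replicate 1 (0.215) or Lgr5-T8- replicate 2 (0.17). Fabp4 passed the threshold no more without Lgr5-T8- replicate 1 (0.102) or Lgr5-T8- replicate 2 (0.0737). Coch passed the threshold no more without Lgr5+T8hi replicate 2 (0.0558). Serpinb2 passed the threshold no more without Lgr5+T8hi replicate 1 (0.16) or Lgr5-T8- replicate 2 (0.0616). Trpm3 passed the threshold no more without Lgr5+T8hi replicate 1 (0.0823), Lgr5+T8hi replicate 2 (0.0693), Lgr5-T8hi replicate 1 (0.0738) or Lgr5-T8hi replicate 2 (0.0641). St8sia6 passed the threshold no more without Lgr5+T8hi replicate 1 (0.0758) or Lgr5+T8hi replicate 2 (0.0549). Serpinb2 was at -1.51 without Lgr5+T8hi replicate 1.

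In this comparison 1558 genes were higher and 746 lower, and 23 of 33 lists passed camera with the preset correlation, 18 fry and 0 camera with an estimated correlation (12 at an unadjusted p under 0.05). Without the batch block 734 genes passed (612 higher and 122 lower). The total was 862 (697 higher, 165 lower) without Lgr5+T8hi replicate 1, 739 (523 higher, 216 lower) without Lgr5+T8hi replicate 2 and 3230 (1827 higher, 1403 lower) without Lgr5-T8- replicate 2. Named genes no longer called without the block, with that adjusted p, were Ifi205 (0.0908) and St8sia6 (0.0787). Lgr5+T8hi and Lgr5-T8- cells, which differ in both markers, differed in 1837 higher and 1450 lower genes, from Frmpd4 (3.84 ± 0.23) and Ocln (3.54 ± 0.14) to Serpinb2 (-6.38 ± 0.41), Trpm3 (-4.14 ± 0.40) and Eya1 (-4.02 ± 0.22). That count was 931 without the block. It was 1552 (1006 higher, 546 lower) without Lgr5+T8hi replicate 1, 1674 (942 higher, 732 lower) without Lgr5+T8hi replicate 2 and 2307 (1362 higher, 945 lower) without Lgr5-T8- replicate 1. Without Lgr5-T8- replicate 2, which gave 1944 higher and 2081 lower, most called genes were lower.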

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

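Tests on immune cells, luminal progenitors, fewer basal cells, a luminal admixture and both proliferation patterns were chosen after the result was seen, while those on endothelial cells, fibroblasts and other splits of the libraries were not. Each population has 2 libraries, too few to test a single library against the rest of its population.

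Markers of endothelial, immune and fibroblast cells were higher in Lgr5+T8hi libraries than in the other 3 populations (15 of 15, 7 of 16 and 14 of 15 members of the first lists had 1 CPM or more in every population), and the labels name no gate against these cells. Second lists were written from marker knowledge without members of the first, and genes whose value had already been seen were removed after the lists had been tested with them. The second endothelial list had a median of 1.51 (19 of 20 higher, 18 at 1 CPM or more in every population), with its most abundant members Eng at 0.68 and Plvap at 1.52. The immune list had a median of 1.35 (7 of 12 higher, 6 at 1 CPM or more in every population, 2 also in another fixed list; 1.56 and 12 of 17 with the seen genes), with Ptpn6 at 0.38 and Cxcr4 at 0.09, and the fibroblast list 0.94 (14 of 20 higher, 19 at 1 CPM or more, 1 also in another fixed list), although Col14a1 (0.03) and Lamb1 (-0.14), abundant in every population, stayed near 0. Cells of these types, or their RNA, are consistent with each list, although genes as abundant in every population as Cxcr4 and Col14a1 would hide a small share, while expression of these genes by Lgr5+T8hi basal cells themselves was not tested and stays open.

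Contractile genes were lower and luminal progenitor genes higher in T8hi cells, which could come from fewer basal or more luminal cells. Fewer basal cells would lower basal markers like contractile genes. The basal median was -0.15 (95% bootstrap interval over genes, not libraries, -0.25 to -0.018) against -0.48. By batch these were -0.12 and -0.16 against -0.47 and -0.48, which argues against this as the whole cause. A luminal admixture of 1 makeup would move progenitor and hormone-sensing genes alike between Lgr5+T8hi and Lgr5-T8hi. But the first median minus the second was -1.0 (interval over genes -1.31 to -0.30). A second luminal progenitor list had a median of 0.65 (7 of 16 higher, and 0.77 with 2 genes seen before), with abundant Chil1 at 0.76 and Plet1 at 0.79. Luminal progenitor cells and a difference of the basal cells themselves cannot be told apart for these genes, because either could raise such a list. The median also lay between the bounds of 0.3 and 0.7 set for it, but above 0.7 with the 2 genes seen before.

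Proliferation genes had a lower median in the T8hi populations, and Lgr5+T8- replicate 2 stood highest in them. A first version of the test set a bound of -0.25 on the median without that library, and the value was -0.249, so the comparison within batch 1, which does not hold that library, was chosen after this value had been seen. Within batch 1 the median was -0.34, with 35 of 40 genes below 0, against -0.62 and 36 in batch 2, which argues against that library as the whole cause of the median. The number of lower genes was 9 with all libraries, 1 without that library, and 6 without Lgr5+T8hi replicate 1, 0 without Lgr5+T8hi replicate 2, 3 without Lgr5-T8hi replicate 1, 3 without Lgr5-T8hi replicate 2, 28 without Lgr5+T8- replicate 1, 5 without Lgr5-T8- replicate 1 and 17 without Lgr5-T8- replicate 2. The number fell as far without Lgr5+T8hi replicate 2, which Lgr5+T8- replicate 2 as the only cause would not give, but with 9 genes, and counts that rose without other libraries, the part of each library cannot be told apart, and a biological difference of Tspan8 stays open as untested.

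There are 18 splits of the 8 libraries into 4 and 4 that are balanced over the batches, too few for a share under 0.05, since the smallest is 0.0556. Fitted without populations, the Tspan8 split gave 290 genes and the highest other split 1, with 1 split as large. The Lgr5 split gave 1 gene and the highest other 290, which was the Tspan8 split, so that 2 splits were as large.

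The test of the interaction itself found that the Tspan8 effect differed with Lgr5 status for 421 genes by edgeR. Among genes named in the text, the log2 difference was largest for Serpinb2 5.41, Il1r2 4.43, Hbb-b1 3.90, Lars2 3.43, Pappa2 2.90, Sema3g 2.72, Zfhx4 2.56 and Col9a1 2.27. Next came Nrp1 2.25, Igf2 2.21, Ptprc 2.12, Cd34 1.89, Emcn 1.85, Il33 1.82, Myocd 1.78 and Notch3 1.45. Lower still were Dcn 1.45, Sema3d 1.36, Dio2 1.29, Tbx2 1.11, Nrg1 1.05, Lpl 1.04, Cxcl10 0.94 and Col4a1 0.83. The smallest were Col1a2 0.81 and Igfbp2 0.78. It was below 0 for Frmpd4 -1.63, Adamts6 -1.57, Esyt3 -1.52, Ocln -1.51, Lgr5 -1.30, Slpi -1.21, Sstr1 -1.17 and Ptprd -1.11. The others below 0 were Sfrp1 -1.10, Myo5b -1.06, Cxcl2 -0.81 and Ntn4 -0.61. By camera with the preset correlation, lists with a difference had medians led by erythroid genes 3.73, immune cell genes 1.96, endothelial genes 1.91, pericyte genes 1.15, adipocyte genes 1.04 and hormone-sensing luminal genes 0.73. Next came epithelial-mesenchymal transition factors 0.47, fibroblast genes 0.45, basement membrane genes 0.25, HOX and positional transcription factors 0.23, extracellular matrix remodelling genes 0.18 and neuronal guidance genes 0.17. Smaller still were epidermal keratinocyte genes 0.16, interferon-stimulated genes 0.14, smooth-muscle contractile genes 0.070 and chemokines, cytokines and receptors 0.042. Below 0 were reported mammary stem cell markers -0.036, oxidative phosphorylation genes -0.086, cholesterol synthesis genes -0.20, cytosolic ribosomal protein genes -0.20, pan-luminal genes -0.23 and proliferation genes -0.45. Of these lists, camera called the stem cell markers higher although their median lay below 0 (mean 0.39, 3 members higher and 0 lower). Medians in batches 1 and 2 had opposite signs for epidermal keratinocyte genes (0.72 and -0.10), proliferation genes (0.25 and -1.16), extracellular matrix remodelling genes (-0.038 and 0.24), chemokines, cytokines and receptors (-0.082 and 0.10), cholesterol synthesis genes (0.20 and -0.65) and HOX and positional transcription factors (-0.073 and 0.72). They had 1 sign but lay over 3 times apart for hormone-sensing luminal genes (0.20 and 0.63), pan-luminal genes (-0.28 and -0.036), fibroblast genes (0.16 and 1.07) and basement membrane genes (0.46 and 0.078). With an estimated correlation camera called 0 of these lists, with 8 at an unadjusted p under 0.05 and 6 by fry.

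Of the 22 lists with a difference, 18 kept their call without Lgr5+T8hi replicate 1, 18 without Lgr5+T8hi replicate 2, 19 without Lgr5-T8hi replicate 1, 17 without Lgr5-T8hi replicate 2, 18 without Lgr5+T8- replicate 1, 17 without Lgr5+T8- replicate 2, 17 without Lgr5-T8- replicate 1 and 15 without Lgr5-T8- replicate 2. The median is given where it moved by over 1.5 times or the call ended, which then has camera's adjusted p in brackets. For reported mammary stem cell markers, which kept their call, it was -0.0084 to 0.091. For hormone-sensing luminal genes it was 0.38 (0.0769) without Lgr5+T8hi replicate 2, 0.28 without Lgr5+T8- replicate 2 and 0.48 without Lgr5-T8- replicate 1. For epithelial-mesenchymal transition factors it was 0.73 without Lgr5+T8- replicate 1. For fibroblast genes it was 0.70 without Lgr5+T8hi replicate 1, 0.25 without Lgr5+T8hi replicate 2, 0.78 without Lgr5-T8hi replicate 1, 0.22 without Lgr5-T8hi replicate 2, 0.78 without Lgr5-T8- replicate 1 and 0.27 without Lgr5-T8- replicate 2. For HOX and positional transcription factors it was 0.37 without Lgr5-T8hi replicate 1, 0.12 without Lgr5-T8hi replicate 2, 0.45 without Lgr5+T8- replicate 1, 0.19 (0.118) without Lgr5+T8- replicate 2, 0.53 without Lgr5-T8- replicate 1 and 0.045 (0.203) without Lgr5-T8- replicate 2. For extracellular matrix remodelling genes it was 0.15 (0.112) without Lgr5-T8hi replicate 2, 0.11 without Lgr5+T8- replicate 2, 0.28 without Lgr5-T8- replicate 1 and 0.12 (0.0937) without Lgr5-T8- replicate 2. For neuronal guidance genes it was 0.27 without Lgr5+T8hi replicate 1, 0.11 without Lgr5+T8hi replicate 2 and 0.29 without Lgr5-T8hi replicate 1. For epidermal keratinocyte genes it was 0.16 (0.668) without Lgr5+T8hi replicate 1, 0.38 without Lgr5+T8hi replicate 2, 0.17 (0.0564) without Lgr5-T8hi replicate 1, 0.058 (0.596) without Lgr5+T8- replicate 1, 0.57 without Lgr5+T8- replicate 2, 0.15 (0.0915) without Lgr5-T8- replicate 1 and 0.38 (0.057) without Lgr5-T8- replicate 2. For interferon-stimulated genes it was 0.23 without Lgr5+T8hi replicate 1, 0.086 without Lgr5+T8hi replicate 2, 0.26 without Lgr5-T8hi replicate 1, 0.26 without Lgr5-T8hi replicate 2, 0.29 without Lgr5+T8- replicate 2, 0.32 without Lgr5-T8- replicate 1 and 0.22 without Lgr5-T8- replicate 2. For smooth-muscle contractile genes it was 0.12 (0.0738) without Lgr5+T8hi replicate 1, 0.064 (0.0553) without Lgr5+T8hi replicate 2, 0.084 (0.108) without Lgr5-T8hi replicate 1, 0.064 (0.112) without Lgr5-T8hi replicate 2, 0.14 without Lgr5+T8- replicate 1, 0.078 (0.175) without Lgr5+T8- replicate 2, 0.16 without Lgr5-T8- replicate 1 and 0.051 (0.181) without Lgr5-T8- replicate 2. For chemokines, cytokines and receptors it was -0.050 (0.0695) without Lgr5+T8hi replicate 1, 0.055 (0.0875) without Lgr5-T8hi replicate 1, 0.014 without Lgr5-T8hi replicate 2, 0.11 (0.0794) without Lgr5+T8- replicate 1, -0.040 (0.134) without Lgr5+T8- replicate 2, 0.14 (0.0768) without Lgr5-T8- replicate 1 and -0.035 (0.304) without Lgr5-T8- replicate 2. For oxidative phosphorylation genes it was -0.18 without Lgr5+T8hi replicate 1, 0.026 (0.661) without Lgr5+T8hi replicate 2, -0.087 (0.112) without Lgr5-T8hi replicate 2, -0.041 (0.184) without Lgr5+T8- replicate 1, 0.040 (0.454) without Lgr5-T8- replicate 1 and -0.21 without Lgr5-T8- replicate 2. For cholesterol synthesis genes it was -0.13 (0.0605) without Lgr5+T8hi replicate 2, -0.16 (0.121) without Lgr5-T8hi replicate 2, -0.37 without Lgr5+T8- replicate 1, -0.018 (0.713) without Lgr5+T8- replicate 2, -0.46 without Lgr5-T8- replicate 1 and 0.051 (0.883) without Lgr5-T8- replicate 2. For cytosolic ribosomal protein genes it was -0.11 without Lgr5+T8hi replicate 2, -0.091 without Lgr5+T8- replicate 1, -0.021 (0.454) without Lgr5-T8- replicate 1 and -0.37 without Lgr5-T8- replicate 2. For pan-luminal genes it was -0.19 (0.142) without Lgr5+T8hi replicate 1, -0.21 (0.112) without Lgr5-T8hi replicate 2, -0.088 (0.787) without Lgr5+T8- replicate 1 and -0.16 (0.0863) without Lgr5-T8- replicate 1.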

How the results depend on the processing

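Removing the batch block lowered the counts most. Without it, edgeR and limma-voom (the latter chosen after seeing the data) called 705 and 612 genes for Tspan8, 219 and 198 genes for Lgr5 and 1 and 1 genes for the interaction. In the simple effects they called 512 and 433 for Tspan8 in Lgr5+ cells and 147 and 142 in Lgr5- cells. For Lgr5 they called 0 and 0 in T8hi and 208 and 170 in T8- cells. For Lgr5+T8hi cells the counts were 931 and 916 against Lgr5-T8- and 734 and 772 against the other 3. With the block, edgeR called 2421, 1502, 421, 1560, 1167, 552, 1464, 3287 and 2304 in the same order. For the 0 in T8hi cells, 1094 and 1167 genes had an unadjusted p under 0.05. Fewer calls go with the larger spread when batch is left in the residual, since the coefficient of variation rises from 0.0928 to 0.192. Over fits that left out 1 library, counts ranged from 1426 to 3353 for Tspan8, from 720 to 2596 for Lgr5 and from 110 to 570 for the interaction. They ranged from 614 to 2088 for Tspan8 in Lgr5+ cells and from 546 to 1927 for Tspan8 in Lgr5- cells. The Lgr5 effects ranged from 39 to 931 for Lgr5 in T8hi cells and from 741 to 2309 for Lgr5 in T8- cells. Counts were from 1552 to 4025 for Lgr5+T8hi against Lgr5-T8- and from 739 to 3230 for Lgr5+T8hi against the other 3. RLE normalization, no count filter, the stricter filter, DESeq2 and limma-voom with the block each kept every total within 1.5 times, but lower genes in the interaction went from 60 to 91 with no filter and 39 with the stricter one. No scaling moved the median of all genes by over 0.1.

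With an estimated correlation camera called 0, 0, 0 and 0 lists for Tspan8, Lgr5, the interaction and Lgr5+T8hi against the other 3, with 14, 1, 8 and 12 at an unadjusted p under 0.05. Leaving out 1 library gave 22 to 27, 9 to 12, 17 to 20 and 21 to 24 lists. The stricter filter raised the correlation of the Tspan8 effects to 0.478 and of the Lgr5 effects to 0.275, as fewer low genes enter. With 1 library left out they were 0.24 to 0.32 and 0.034 to 0.21. Some list medians near 0 changed sign with 1 library left out, and the cause was not tested. The ribosomal median ranged over -0.040 to 0.10 for Tspan8, -0.094 to 0.079 for Lgr5 and -0.13 to 0.032 for Lgr5+T8hi against the other 3, and that of oxidative phosphorylation genes over -0.21 to 0.040 for the interaction and -0.19 to 0.012 for Lgr5+T8hi against the other 3.

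Of 160 results on named genes, 0 reversed under any alternative, 42 lost their call without the block (49 with limma-voom), 11 with no count filter and 4 with limma-voom and the block. Between 2 and 14 lost it when 1 library was left out. The stricter filter kept 153 of these results and their calls. Of 132 list results, 4 lost their call without the block, 3 with RLE and 79 with an estimated correlation. With 1 library left out, 5 to 12 lost it, 2 to 9 gained one and 0 to 3 reversed. Depth limits genes near 0.122 CPM.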

Other observations

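The motile cilia test was set before its values were seen, and the Hedgehog and chromosomal neighbourhood tests after the result was seen. Within T8hi cells, the luminal lists went in different directions with Lgr5. Luminal progenitor and milk genes gave 0 higher and 5 lower of 16 (1 and 8 adjusted over the list alone, median -0.46, camera adjusted p = 3.56e-08, 0.247 with an estimated correlation), while hormone-sensing luminal genes gave 2 higher and 1 lower of 17 (6 and 2 adjusted over the list alone, median 0.54, camera adjusted p = 0.00905, 0.448 with an estimated correlation). Pan-luminal genes gave 1 higher and 0 lower of 15 (1 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.0657, 0.516 with an estimated correlation). Among abundant genes of the second luminal progenitor list, chosen here after their values were seen, Chil1 stood at 1718 CPM in Lgr5-T8hi and 733 in Lgr5+T8hi cells, against 529.6 in Lgr5+T8- and 826 in Lgr5-T8- cells. Plet1 stood at 392, 362, 245 and 190.3 CPM in the same order.

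Several motile cilia genes were higher in Lgr5+ cells, and a cilia gene program that differs with Lgr5 is a candidate explanation. Over 32 cilia genes other than those first noticed, the median log2 difference was 0.39 (quartiles 0.29 and 0.71), 9 passed edgeR as higher and 0 as lower, and limma's fry gave an adjusted p = 0.0105 over the 6 second lists. Foxj1, the master regulator of motile cilia, was the most abundant at 198 CPM in Lgr5+T8hi, 161 in Lgr5-T8hi, 176 in Lgr5+T8- and 88.5 in Lgr5-T8- cells, a difference of 0.64 (edgeR adjusted p = 0.0045). Enkur was at 0.80, Rsph9 at 0.73 and Ccdc114 at 0.70, while Rfx3 was at -0.032 and Cfap100 lowest at -0.69. These members were picked after their values were seen, and 18 of 32 had 1 CPM or more in every population.

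Gli1 and Gli2 were higher in Lgr5+ cells, which might reflect a Hedgehog pathway difference. Over 16 other pathway genes the median was -0.13 (quartiles -0.19 and 0.06; -0.12 with 1 gene seen before), with 0 higher and 0 lower by edgeR and a fry adjusted p of 0.184 from limma, which argues against a change of the whole list. The direct target Ptch1 was at 0.15.

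Lgr5 and Tspan8 lie 229037 bases apart on chromosome 10, and both were higher in Lgr5+T8hi than in Lgr5-T8- cells, so a change along the whole neighbourhood could be a common source. Of 11 other genes tested within 1000000 bases of either, 0 passed as higher with Tspan8 or Lgr5 by edgeR. Those before Lgr5 were at -0.19 to 0.03 with Tspan8 and -0.23 to 0.11 with Lgr5, which argues against it. A930009A15Rik, inside the span of Lgr5, was at 0.15 with Tspan8 and 0.68 with Lgr5 (edgeR adjusted p = 0.808 and 0.222). Beside Tspan8, Ptprr and Ptprb were at 1.22 with Tspan8 (edgeR adjusted p = 0.144 and 0.0606). Farther from Tspan8, Kcnmb4 and Cnot2 were at -0.17 and -0.03 with it. A change in part was not tested and stays open.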
